A study of Mus musculus with 6 samples.

How the data were processed

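RNA from 6 samples of mouse neural progenitor cells was hybridised to Affymetrix arrays, 1 array per sample, after biotin labelling, per the labels' protocols. The cells were derived from mouse embryonic stem (ES) cells that carry GFP in the Sox1 locus, with or without an added Sox3 transgene driven by the Nestin promoter. They were grown as monolayers for 4 days with 0.5 µM retinoic acid given on days 0 and 2, then sorted by FACS on day 4, per the labels' protocols. There were 3 samples labelled as biological replicates in each group. The labels do not say whether samples with the same number shared a culture, a sort or a day, nor whether each genotype was 1 ES cell clone or several.

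The deposited table holds log2 expression values, 1 per probe set and array, that the authors made with RMA in Affymetrix Power Tools, per the submitters' processing notes. RMA corrects the background, quantile-normalises probe intensities between arrays and summarises the probes of a probe set on the log2 scale. The versions of the tools, the array type and the probe set definition are not given in the sources used here. The values ran from 4.41 to 14.6, none were centred per gene, and no detection call or background estimate came with them. A probe set near the lower end of this range therefore has no stated detection limit, and RMA is known to compress the fold changes of dim genes. Depth does not apply to array values; the precision is set by the 3 arrays per group.

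Of the 21940 deposited probe sets, 64 are array controls and were left out of the tests. The other 21876 are named by RefSeq transcript accession. These were matched without version numbers to a RefSeq gene table (GRCm38.p6), which was used for gene names only, so no coordinates are given. The match gave 1 symbol for 17123 probe sets, several symbols for 0, and no symbol for 4753, most of them old predicted transcripts. The named probe sets cover 15302 genes. Many accessions share all their probes: the tested probe sets hold 18009 distinct profiles, and 3867 probe sets repeat the values of another. The values of 101 genes are identical to those of another gene, so those genes cannot be told apart; 0 of the 82 called genes chosen by the naming rule is among them. Each gene is represented by its probe set with the highest mean over all 6 arrays.

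The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on the deposited log2 values, no replicate block, no filter on dim probe sets, two-sided). Adjusted p is the Benjamini-Hochberg value over all 21876 probe sets, and the threshold was 0.05. Differences are given as Sox3 over-expression minus control, with limma's moderated standard error (SE). For 25 gene lists, fixed before the data were examined, the shift of a whole list against the other genes was tested with camera (preset inter-gene correlation 0.01, Benjamini-Hochberg over the 25 lists), and the members past the gene-wise threshold were counted, also with the adjustment over the list alone. Of the 743 list entries, 681 were measured. No list call held with a correlation estimated from these arrays. Because the log2 differences followed the signal level, the median of each list was also placed among 10000 random lists matched on mean signal in 20 bins.

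The genes named were chosen by a rule fixed at the same time. They are Sox1, Sox2, Sox3, Nes and Pax6, the 12 highest and the 12 lowest log2 differences among called genes whose arrays did not overlap between the groups, and from each list up to 4 called members by smallest p, or the 2 members with the largest difference where none was called. Not every gene that the rule chose is named. Genes outside this rule are marked as chosen after their values were seen.

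The procedure was tested on simulated data. For this comparison, 18009 simulated profiles held 200 changed genes, and 10 such sets were drawn. They had the real means, but the real spreads were first moderated toward a common value, as in limma. Recovery at the unmoderated spreads was not simulated. The test recovered 89.8% of changes of 0.4 on the log2 scale, 99.2% of those of 0.6 and 99.8% of those of 1; 6.43% of the calls were false on average. Planted lists of 20 changed genes were called in 10 of 10 sets. The noise was drawn independently for each gene, and all planted members rose by at least 0.4. The simulation therefore says nothing on lists whose genes are correlated or in which few members change.

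The replicate numbers were not treated as pairs, since the labels do not say that they are. The deviations of same-numbered arrays from their group means correlated at 0.29, -0.21 and 0.09. The same comparison was repeated with quantile normalisation or median centring of the deposited values, with filters at the 25th percentile and at the median of mean signal, another variance model, array weights, a replicate block, stricter thresholds, other set tests, probe set averaging, named probe sets alone and leaving out each array. Cyclic loess between arrays and counting identical profiles once were added after seeing the data.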

Results

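Gene expression was measured on 6 arrays of sorted Sox1-GFP cells labelled as neural progenitor cells. Of these, 3 were from cells with the Nestin-Sox3 transgene and 3 from control cells without it. Sox3 is a SoxB1 transcription factor of neural progenitors, and Nestin is an intermediate filament protein whose promoter is active in these cells. The comparison asks which genes differ in expression when Sox3 is over-expressed. Whether each genotype came from 1 ES cell clone or several is not stated, and a difference between clones, in imprinted genes for example, would be measured as one between genotypes. The median log2 signal lay between 6.85 and 6.87 on all 6 arrays. The interquartile range lay between 2.89 and 3.02 on 5 arrays and was 3.17 on control replicate 3. Pairwise correlations of arrays across probe sets were 0.996 to 0.999 within groups and 0.993 to 0.997 between groups. Control replicate 3 lay apart on the axis of largest variance, which held 59.2% of it, at 22.4 against 4.83 and 6.04 for the other control arrays and -15.3 to -7.91 for the Sox3 arrays.

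Sox3 itself was 3.39-fold higher in the cells with the transgene. Its mean log2 signal was 9.22 ± 0.01 (SD, n = 3) against 7.45 ± 0.18 (SD, n = 3), a difference of 1.76 ± 0.08 (SE; limma adjusted p = 0.000189). All 3 Sox3 arrays lay above all 3 control arrays, so the labels hold for the targeted gene, as far as the probed sequence is part of the transgene, which the sources used here do not state. Sox2, the closely related SoxB1 factor, fell by 0.37 ± 0.06 on the log2 scale (SE, n = 3 per group; limma adjusted p = 0.024). The Sox2 call was lost, with adjusted p up to 0.075, when any of the 3 Sox3 arrays or control replicate 1 was left out, and under cyclic loess, where the difference was -0.29 (adjusted p = 0.053); over all settings its adjusted p ran from 0.011 to 0.075. Sox1, the gene at the GFP-tagged locus used for sorting, was at 6.86 ± 0.12 in Sox3 cells and 6.96 ± 0.11 in control cells (SD, n = 3 each; limma adjusted p = 0.46). Nes, which encodes Nestin, was at 8.15 ± 0.08 and 8.02 ± 0.06 (SD, n = 3 each; limma adjusted p = 0.21). Pax6, a homeobox factor of neural progenitors, was at 5.86 ± 0.03 and 6.05 ± 0.04 (SD, n = 3 each; limma adjusted p = 0.068), a difference of -0.19 that passed the threshold after quantile normalisation (-0.24, adjusted p = 0.028) but not in most settings (adjusted p from 0.010 to 0.21).

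The genes that rose most beside Sox3 were Neurog2, Prdm8, Tagln, Fgfbp3 and Acta2. Neurog2, a proneural bHLH factor, was 3.38-fold higher (log2 difference 1.76 ± 0.06 SE, limma adjusted p = 4.27e-05), and Prdm8, a PRDM-family zinc finger factor, was 3.26-fold higher (1.71 ± 0.11 SE, limma adjusted p = 0.000829). Tagln and Acta2, actin-associated and actin genes of contractile cells, were 2.69-fold and 2.25-fold higher, and Cnn2, the actin-binding calponin 2, was 2.24-fold higher. Fgfbp3, a secreted FGF-binding protein, rose 2.37-fold, the protocadherin gene Pcdh8 2.14-fold, Pmp22, a membrane protein gene, 2.09-fold, and the angiotensin receptor gene Agtr1a 2.03-fold. Pmaip1, which encodes the pro-apoptotic protein Noxa, rose 1.94-fold and Lhfp 1.94-fold. The SEs of these 12 log2 differences were 0.06 to 0.16.

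The deepest fall was that of Crabp1, a cellular retinoic acid binding protein, whose signal was 3.05-fold lower (log2 difference -1.61 ± 0.10 SE, limma adjusted p = 0.000876). Lefty2, a secreted Nodal antagonist, was 2.08-fold lower, and Cubn, the endocytic receptor cubilin, 2-fold lower. Gm20767 was 1.98-fold and 6330403K07Rik 1.88-fold lower. Igfbp4, an IGF-binding protein, was 1.84-fold lower, the RNA-binding protein gene Igf2bp3 1.82-fold, and the hyaluronan synthase gene Has2 1.80-fold. Pxylp1 and Egln3, a HIF prolyl hydroxylase, were each 1.76-fold lower. The SEs of the 12 lowest log2 differences, of which 10 are named here, were 0.06 to 0.17, with limma adjusted p up to 0.012. Of the 12 highest and 12 lowest, 21 of 24 kept their call in all 6 fits that left out 1 array; the exceptions were Lefty2 (lost without Sox3 replicate 1, adjusted p = 0.0505), and Cubn and Pxylp1 (each lost without Sox3 replicate 1 or 2, adjusted p up to 0.058 and 0.062).

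**Figure D1:**
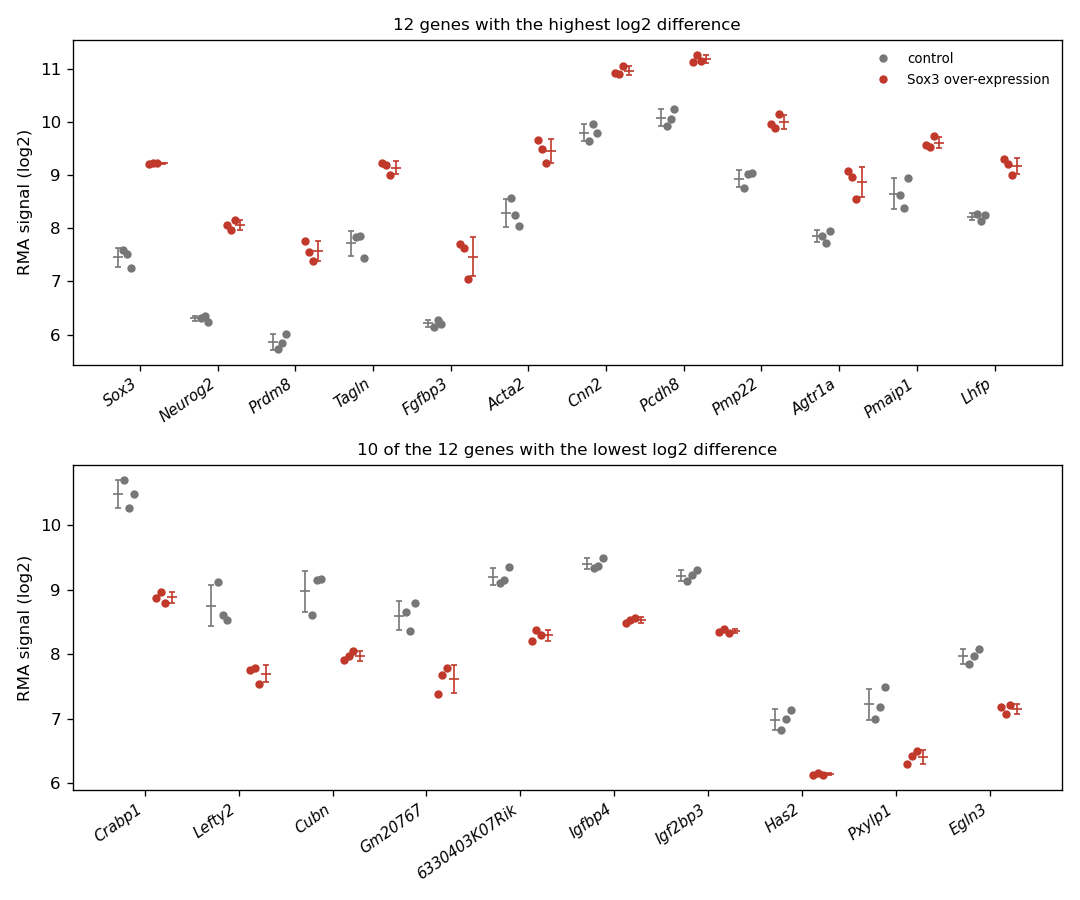
RMA signal (log2) of the 12 genes with the highest (upper panel) and 10 of the 12 with the lowest (lower panel) log2 difference, for 3 control arrays (grey) and 3 Sox3 over-expression arrays (red); each point is 1 array, and bars beside them show mean ± SD. In every gene shown, the 3 arrays of one group lay on one side of the 3 arrays of the other, and Sox3 was at 9.22 against 7.45 on average.

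In all, 195 genes rose and 408 fell at an adjusted p under 0.05, which corresponds to 255 and 536 probe sets. Of these genes, 35 were at least 1.5-fold higher and 52 at least 1.5-fold lower, and 10 and 3 reached 2-fold. The differences followed the signal: the median log2 difference was between 0.02 and 0.05 in the 5 dimmer deciles of genes and between -0.02 and -0.08 in the 5 brighter ones. Probe sets that rose made up 32.2% of the calls with the deposited values and 43.4% after quantile normalisation (382 higher, 498 lower). With 5 arrays there were fewer calls: 94 higher and 94 lower without Sox3 replicate 1, 74 and 131 without replicate 2, and 127 and 217 without replicate 3. There were 141 and 277 without control replicate 1, 99 and 210 without replicate 2, and 189 and 286 without replicate 3. Of the 82 called genes chosen by the naming rule, 41 kept their call in all 6 of these fits. Of the 81 other than Sox3, 43, 46 and 60 kept it without Sox3 replicates 1, 2 and 3, and 65, 57 and 72 without control replicates 1, 2 and 3.

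Neural progenitor genes went both ways. Of 38 measured SoxB1 and progenitor genes, 4 rose and 5 fell (6 and 11 adjusted over the list alone), and the list as a whole did not shift (camera adjusted p = 0.79; the median log2 difference was -0.02, the mean 0.03). Sox21, a SoxB2 factor, rose 1.78-fold (log2 difference 0.84 ± 0.08 SE) together with Sox3 and Fgfbp3, while Irx3, an Iroquois homeobox gene, was 1.71-fold lower (-0.77 ± 0.10 SE). Of 22 proneural genes 3 rose (3 adjusted over the list alone) and the other 19 did not pass. They were Neurog2, Olig2, a bHLH factor of ventral progenitors, which was 1.72-fold higher, and the antiproliferative gene Btg2, 1.30-fold higher, whose call was lost without Sox3 replicate 2 (limma adjusted p = 0.0501). The proneural list shifted upward with a median log2 difference of 0.11 (camera adjusted p = 0.000345; adjusted p = 0.23 with an estimated correlation), and its median lay at percentile 99.9 of signal-matched random lists. That percentile is no separate support, since the random lists held genes drawn independently and take no account of correlation within a list. The pluripotency and epiblast lists, which were not called, lay at percentiles 99.95 and 98.7. Among the 19 proneural genes that did not pass, the log2 differences ran from -0.14 ± 0.05 for Neurog3 to 0.22 ± 0.08 for Olig1 (SE), a pair chosen after their values were seen.

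Of 49 neuronal differentiation genes, 2 rose and 3 fell (4 and 8 adjusted over the list alone; camera adjusted p = 0.61). The fallen genes included Nsg2, which was 1.57-fold lower, Crmp1, 1.40-fold lower, and the neurofilament gene Nefm, 1.42-fold lower, whereas Stmn4, a stathmin gene, rose 1.34-fold. With 1 array left out, the calls of Crmp1, Nefm and Stmn4 were lost without Sox3 replicate 2, those of Nefm and Stmn4 also without Sox3 replicate 1, and further that of Nefm without Sox3 replicate 3 and that of Stmn4 without control replicate 2 (limma adjusted p up to 0.0501, 0.097 and 0.089). In the Notch pathway list, 1 of 23 genes rose and 1 fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.19). These were Rbpj, the nuclear effector of Notch, 1.21-fold higher, and the non-canonical ligand gene Dlk1, 1.29-fold lower; the Rbpj call was lost under median centring and the Dlk1 call under cyclic loess (limma adjusted p = 0.0507 and 0.0501). With 1 array left out, Rbpj lost its call in all 6 fits and Dlk1 in all but that without control replicate 3 (limma adjusted p up to 0.12 and 0.10). Of 25 glial genes 1 rose and 1 fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.41): Id4, an inhibitor of bHLH factors, was 1.67-fold higher and Aldoc, an aldolase gene, 1.62-fold lower.

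Genes of the retinoic acid response were mixed, with 2 of 24 higher and 4 lower (3 and 7 adjusted over the list alone; camera adjusted p = 0.13). Beside Crabp1, the nuclear receptor gene Nr2f1 was 1.73-fold lower and the homeobox gene Meis2 1.39-fold lower, while Aldh1a1, a retinaldehyde dehydrogenase gene, rose 1.24-fold. The Meis2 and Nr2f1 calls were lost without Sox3 replicate 1 or 2, that of Nr2f1 also without replicate 3, and that of Aldh1a1 without any 1 of the 6 arrays (limma adjusted p up to 0.079, 0.072 and 0.097). Stra8, another called member and chosen after its value was seen, fell by 0.34 ± 0.06 on the log2 scale (SE, limma adjusted p = 0.031). Of 34 Hox genes, 1 rose and 4 fell (2 and 4 adjusted over the list alone; camera adjusted p = 0.61; the median log2 difference was 0.03, the mean -0.01). Hoxd8 was 1.58-fold higher, and Hoxb1 1.69-fold, Hoxc4 1.52-fold and Hoxb9 1.29-fold lower; the Hoxb9 call was lost without Sox3 replicate 1 or 2 (limma adjusted p up to 0.070). None of 30 forebrain and midbrain genes passed (0 adjusted over the list alone, 4 at an unadjusted p under 0.05 in limma's test; camera adjusted p = 0.25), and the largest differences were 0.23 ± 0.09 for Lmx1b and 0.21 ± 0.07 for Vax2 (SE). In the ventral neural tube list 1 of 24 genes rose, Olig2, and 1 fell, Foxa2, the floor plate and endoderm factor (2 and 3 adjusted over the list alone; camera adjusted p = 0.79). In the dorsal list the R-spondin gene Rspo2 rose 1.25-fold and Rspo3 was 1.61-fold lower, with 22 of 24 genes not passing (2 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.31). With 1 array left out, the calls of Rspo2, Rspo3 and Foxa2 were each lost without Sox3 replicate 1, Sox3 replicate 2 or control replicate 2, and in some cases without others (limma adjusted p up to 0.071, 0.14 and 0.12).

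Markers of other lineages were called in a minority of each list. In each of these lists the share called was above that over all measured genes, 603 of 15302. Some members were bright in both groups. Mean log2 signals in Sox3 and control cells were 13.5 and 13.6 for Dppa5a, 12.6 and 12.6 for Zfp42, and 9.97 and 9.93 for Sox7. Others, such as Dppa3 at 6.68 and 6.58, were not. These 4 genes were chosen after their values were seen. Whether the mix of cells in the sorted population differed between the groups was not tested. At an unadjusted p under 0.05 in limma's test, 15 of the 28 pluripotency genes passed. The median of that list lay at percentile 99.95 of signal-matched random lists, although the list was not called. Of 28 pluripotency genes 1 rose and 4 fell (5 and 7 adjusted over the list alone; camera adjusted p = 0.79; the median log2 difference was 0.03, the mean -0.04). The orphan receptor gene Nr0b1 was 1.52-fold higher, and Lefty2, Lefty1 (1.52-fold) and Prdm14 (1.36-fold) were lower; the Prdm14 call was lost after quantile normalisation (limma adjusted p = 0.057). Among 14 epiblast genes 3 rose and 1 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.092): Pou3f1 was 1.39-fold, Etv4 1.25-fold and Foxd3 1.28-fold higher, and the DNA methyltransferase gene Dnmt3a 1.42-fold lower. Of 30 endoderm genes 4 fell (6 adjusted over the list alone) while the list did not shift (camera adjusted p = 0.62). These were Cubn, Afp, which encodes alpha-fetoprotein and was 1.48-fold lower, Ttr, transthyretin, 1.22-fold lower, and Foxa2, 1.49-fold lower; Afp and Ttr lay near the dim end, at 4.94 and 5.76 in Sox3 cells. In the mesoderm list 2 of 35 genes rose and 4 fell (2 and 4 adjusted over the list alone; camera adjusted p = 0.13). Tagln and Acta2 rose, whereas the forkhead gene Foxc2 was 1.39-fold lower and the collagen gene Col1a2 1.32-fold lower. Of 33 neural crest and surface ectoderm genes 2 rose and 2 fell (2 and 3 adjusted over the list alone; camera adjusted p = 0.12): Edn1, endothelin 1, was 1.20-fold and Foxd3 1.28-fold higher, and the keratin genes Krt8 and Krt19 were 1.42-fold and 1.24-fold lower. The Edn1 and Foxd3 calls were lost after quantile normalisation (limma adjusted p = 0.065 and 0.057). Many of these changes lost their call with 5 arrays while keeping their direction: without Sox3 replicate 1 the calls of Lefty1, Lefty2, Prdm14, Etv4, Foxd3, Dnmt3a, Cubn, Afp, Ttr, Foxa2, Edn1, Krt8 and Krt19 were lost (limma adjusted p up to 0.16, for Foxd3). Edn1 and Etv4 lost their call without any 1 of the 6 arrays, and Foxd3 in all fits but that without Sox3 replicate 3, with limma adjusted p up to 0.14, 0.10 and 0.16. Nr0b1, Pou3f1, Tagln, Acta2, Foxc2 and Col1a2 kept theirs in all 6.

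Among signalling targets, 4 of 20 FGF target genes rose (6 higher and 2 lower adjusted over the list alone). The MAP kinase phosphatase gene Dusp6 was 1.56-fold, the FGF antagonist gene Spry4 1.25-fold, and the ETS factor genes Etv4 and Etv5 1.25-fold and 1.22-fold higher, and the list shift did not pass (camera adjusted p = 0.073). The Dusp6 and Etv4 calls were lost under median centring (limma adjusted p = 0.055 and 0.053). With 1 array left out, Spry4 and Etv4 lost their call in all 6 fits, and Dusp6 and Etv5 in all but that without control replicate 3 (limma adjusted p up to 0.093, 0.10, 0.11 and 0.078). Of 24 Wnt target genes 2 rose and 1 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.79). Sfrp2 and Notum, secreted Wnt antagonists, were 1.59-fold and 1.49-fold higher, and Ccnd1, which encodes cyclin D1, was 1.48-fold lower. The Sfrp2 and Notum calls were lost without Sox3 replicate 1 or 2, and that of Notum also without Sox3 replicate 3 or control replicate 2 (limma adjusted p up to 0.060 and 0.086). Of 21 BMP and TGF-beta target genes 3 rose and 2 fell (4 and 4 adjusted over the list alone; camera adjusted p = 0.86; the median log2 difference was 0.00, the mean -0.02), among them Id4 and Ccn2, a matricellular protein gene 1.41-fold higher, and Tgfbi and Lefty1, 1.59-fold and 1.52-fold lower. The Ccn2 call was lost without Sox3 replicate 1 or 2, that of Tgfbi without Sox3 replicate 1, and that of Lefty1 without Sox3 replicate 1 or 3 or control replicate 1 (limma adjusted p up to 0.060, 0.062 and 0.082).

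Genes of cell cycle exit and p53 targets shifted upward. Of 22 measured, 5 rose and 1 fell (10 and 1 adjusted over the list alone), the median log2 difference was 0.15, and it lay at percentile 100 of signal-matched random lists (camera adjusted p = 4.32e-05; adjusted p = 0.28 with an estimated correlation). Pmaip1 rose 1.94-fold, Perp, a desmosomal p53 target, 1.56-fold and Btg2 1.30-fold, whereas Cdkn1c, an imprinted cyclin-dependent kinase inhibitor gene, was 1.63-fold lower. Of 38 cell cycle genes only Ccnd1 fell (1 higher and 2 lower adjusted over the list alone). That list's downward shift (median -0.07, camera adjusted p = 0.037; adjusted p = 0.74 with an estimated correlation) was lost after quantile normalisation (adjusted p = 0.93) and without Sox3 replicate 1, control replicate 1 or control replicate 3 (adjusted p = 0.50, 0.055 and 0.11), and its median lay at percentile 60.8 of signal-matched lists. Of 26 stress and dissociation genes 1 rose, Atf3, a stress-induced factor gene 1.36-fold higher (1 adjusted over the list alone; camera adjusted p = 0.78; the median log2 difference was 0.02, the mean -0.02). The Atf3 call was lost without Sox3 replicate 1 or 3 or control replicate 1 or 2 (limma adjusted p up to 0.073), and that of Btg2 without Sox3 replicate 2 (0.0501).

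Glycolysis and hypoxia genes, cholesterol synthesis genes and imprinted genes were lower as groups. Of 24 glycolysis and hypoxia genes 8 fell (1 higher and 14 lower adjusted over the list alone) and the median log2 difference was -0.21 (camera adjusted p = 5.47e-06; adjusted p = 0.20 with an estimated correlation). Egln3 was 1.76-fold, Aldoc 1.62-fold, the phosphofructokinase gene Pfkp 1.47-fold and the oxidoreductase gene Ero1a 1.40-fold lower. Of 22 cholesterol synthesis genes 5 fell (9 adjusted over the list alone) and 21 had a difference below 0, with a median of -0.15 (camera adjusted p = 5.47e-06; adjusted p = 0.20 with an estimated correlation). Lss, lanosterol synthase, and Dhcr7, the last enzyme of the pathway, were 1.35-fold and 1.36-fold lower, and Pmvk and Tm7sf2 1.29-fold and 1.28-fold lower. Of 34 imprinted genes 8 fell (13 adjusted over the list alone), with a median of -0.09 (camera adjusted p = 0.000617; adjusted p = 0.20 with an estimated correlation). Cdkn1c was 1.63-fold, Peg3 1.57-fold, Igf2r, the IGF2 clearance receptor gene, 1.49-fold and the non-coding RNA gene Meg3 1.58-fold lower. The medians of these lists lay at percentiles 0, 0.83 and 0.52 of signal-matched lists. The 45 array control probe sets not named for mouse genes had a median log2 difference of -0.19, lower than the medians of the cholesterol and imprinted lists. Of 17 interferon and immune genes 1 fell (1 adjusted over the list alone; camera adjusted p = 0.97), the MHC gene H2-K1, 1.26-fold lower, a call lost after quantile normalisation (limma adjusted p = 0.065). With 1 array left out, the calls of Ero1a, Dhcr7, Pmvk, Tm7sf2 and H2-K1 were lost without Sox3 replicate 1, among others, and that of Meg3 without Sox3 replicate 2 (limma adjusted p up to 0.072, 0.058, 0.085, 0.10, 0.11 and 0.060), whereas Egln3, Aldoc, Pfkp, Lss, Cdkn1c, Peg3 and Igf2r kept theirs in all 6. The list calls carry a limit. With the preset correlation, camera also called between 2 and 9 of the 25 lists in each of the other 9 splits of the 6 arrays into 3 and 3. None of the other splits called a probe set. Each of those splits mixes the genotypes 2 to 1 on both sides, so part of the genotype difference remains and the rest widens the spread. The lack of probe set calls there was nearly fixed in advance, and the list calls there do not come from a comparison without any difference.

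**Figure D2:**
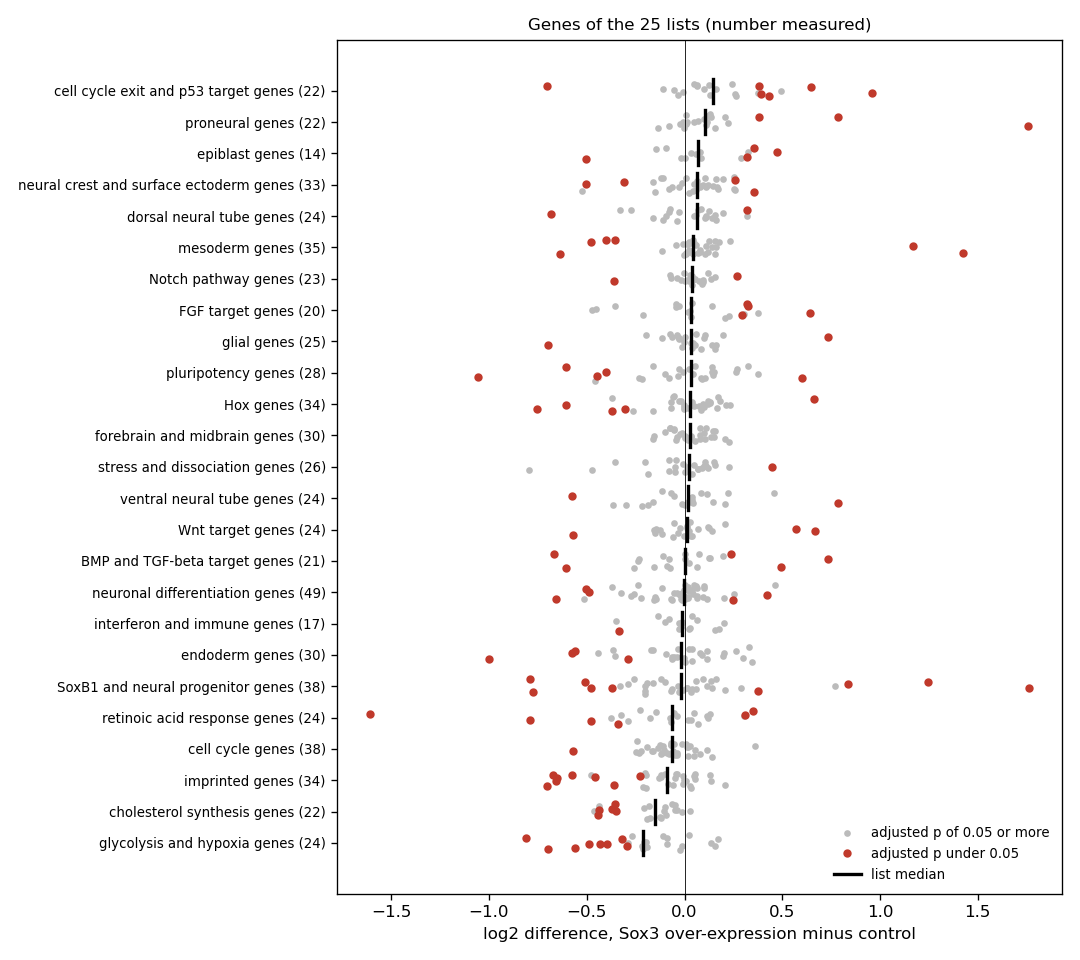
Log2 difference (Sox3 over-expression minus control) of each measured gene of the 25 lists, with the number measured in brackets; red points passed an adjusted p under 0.05, grey points did not, and black bars are list medians. The medians ran from -0.21 for glycolysis and hypoxia genes to 0.15 for cell cycle exit and p53 target genes, and lists such as the retinoic acid response held called genes on both sides of 0.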

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

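Cyclic loess and the single count of identical profiles were chosen after seeing the data. The counts of probe sets stayed within 1.5 times of 255 higher and 536 lower under quantile normalisation, median centring, cyclic loess, both signal filters, the trended variance model, named probe sets alone, identical profiles counted once and the replicate block (248 and 510). Array weights, which gave control replicate 3 a weight of 0.29, raised them to 817 and 1280. Similar counts did not mean the same probe sets. Of the 791 probe sets called with the deposited values, 645 were also called after quantile normalisation and 630 after median centring. Cyclic loess called 622 of them and the replicate block 561. A 1.5-fold limit left 43 and 73, a 2-fold limit 12 and 5, and an adjusted p under 0.01 left 67 and 83. Without eBayes moderation 0 and 0 passed, although 3938 probe sets had an unadjusted p under 0.05; with 4 residual degrees of freedom such a test has little reach. Leaving out 1 array gave 74 to 189 higher and 94 to 286 lower. Probe sets that rose made up 44.5% of calls after cyclic loess. No probe set called with the deposited values turned its sign in any of these fits. For most of the fits this was fixed in advance. Filters and stricter thresholds leave the difference as it is. All 603 called genes had groups that did not overlap, so leaving out 1 array could not turn them. Whether the numbers pair the samples is not known. Same-numbered deviations correlated at 0.29, -0.21 and 0.09 and the others at -0.36 to 0.34, too few values to decide. The replicate block kept 77 of the 81 calls chosen by the naming rule other than that of Sox3; the calls of Edn1 (adjusted p = 0.067), Dlk1 (0.057), Rbpj (0.055) and H2-K1 (0.051) were lost. Quantile normalisation kept 77, median centring 78 and cyclic loess 75 of these 81; 43 to 72 remained when 1 array was left out, and Sox3 passed in each of the fits with eBayes. No named gene turned its direction, which for the called genes was fixed in advance in the fits that left out 1 array.

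With an estimated correlation the camera adjusted p rose to 0.23 for proneural genes, 0.28 for cell cycle exit and p53 target genes, 0.20 for the glycolysis and hypoxia, cholesterol synthesis and imprinted lists, and 0.74 for cell cycle genes. These estimates were 0.017 to 0.41 against the preset 0.01, and this form of the test also takes its degrees of freedom from the 6 arrays, not from the genes. The cell cycle call was also lost under quantile normalisation (0.93), the 25th percentile and median filters (0.14 and 0.58) and array weights (0.29), and turned upward under cyclic loess (0.98). The fry test sets a list against no change and not against the other genes, so its adjusted p answers another question; it passed for neuronal differentiation (downward, 0.044), epiblast (0.0055) and FGF target genes (0.021), and not for cell cycle genes (0.42). New camera calls were, under the 25th percentile filter epiblast (0.041) and FGF (0.024), under the median filter epiblast (0.017), FGF (0.0062) and mesoderm (0.030), and under array weights FGF and retinoic acid genes (0.027 each). The direction of lists that were not called turned, with adjusted p in brackets, under quantile normalisation for glial (0.84), ventral (0.75) and Wnt (0.80) genes, and under cyclic loess for glial (0.91), ventral (0.75) and Wnt (0.81) genes. It also turned under the median filter for glial and Hox (0.965 each), endoderm (0.76), neural crest and surface ectoderm (0.84) and ventral (0.47) genes, and under the 25th percentile filter for progenitor and interferon genes (0.89 each). With all 6 arrays the remaining turns were those of ventral genes under array weights (0.84), Wnt genes in the fry test (0.98) and BMP genes under the replicate block (0.99). The cause was not tested in any of these. When 1 array was left out, the adjusted p ranged from 0.71 to 0.90 for progenitor, 0.048 to 0.70 for Notch, 0.42 to 0.98 for pluripotency, 0.055 to 0.94 for endoderm, 0.035 to 0.30 for retinoic acid, 0.55 to 0.99 for ventral, 0.45 to 0.93 for Wnt, 0.046 to 0.17 for FGF, 0.73 to 0.98 for BMP, 0.0034 to 0.50 for cell cycle, 0.47 to 0.91 for stress and 0.71 to 0.98 for interferon genes. Of these, the direction turned in 12 fits: in 3 for pluripotency, 2 each for BMP and stress, and 1 each for progenitor, endoderm, ventral, Wnt and interferon genes. The other 5 list calls held in all of these fits, with a highest adjusted p of 0.0027. Signal over background was not given, so which dim genes were detected is unknown.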

Other observations

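The tests on collagen genes, on the other retinoic acid response genes and on cyclic loess were chosen after the result was seen. The others were written down before their own results. Some of the latter concern patterns, or an array, that stood out in these data. Tpm1, a tropomyosin gene outside the named set and chosen after its value was seen, rose with Tagln, Acta2 and Cnn2 (log2 difference 0.69 ± 0.05 SE, limma adjusted p = 0.00196). Of 26 other measured actin cytoskeleton and SRF target genes, listed after these 4 had been seen and without them, 5 rose: Ccn1 by 0.45, Thbs1 by 0.34, Cald1 by 0.32, Zyx by 0.22 and Acta1 by 0.21 on the log2 scale. In 19 of the 26 the difference was above 0.

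The rise of Tagln, Acta2, Cnn2 and Tpm1 averaged 1.11 on the log2 scale, for genes chosen after their values were seen. Mesenchymal or smooth muscle cells stay open, although the cells were sorted as Sox1-positive, with a purity that is not given: they would bring fibrillar collagen transcripts, and the mean of Col1a1, Col1a2 and Col3a1 was lower, at -0.23 (95% interval -0.34 to -0.11), but these genes were dim, with differences of 0.08 ± 0.08 for Col1a1, -0.40 ± 0.05 for Col1a2 and -0.35 ± 0.05 for Col3a1 (SE; the latter pair passed the threshold). The signal-dependent offset between the groups was far smaller than this rise, with median log2 differences of -0.08 to 0.05 over the deciles of signal. Cyclic loess kept 107% of the rise, but it could remove only an offset of about that size, so its outcome was fixed in advance. A candidate explanation, as a hypothesis, is a shared actin cytoskeleton programme. The 26 other genes shifted upward (camera p = 0.000163, and 0.031 with an estimated correlation of 0.026). Both p are unadjusted, unlike those given for the 25 lists. Unadjusted camera p with an estimated correlation was 0.023 for glycolysis and hypoxia, 0.014 for cholesterol synthesis and 0.024 for imprinted genes. It was 0.037 for proneural genes and 0.066 for cell cycle exit and p53 targets. The actin list therefore did not pass a check that those lists failed. Differences in plating density or adhesion between the cell lines were not tested and stay open.

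Glycolysis and hypoxia genes and cholesterol synthesis genes were lower in Sox3 cells, a pair of list calls that were lost with an estimated correlation (adjusted p = 0.20 each), and random lists of like signal also had medians below 0, at -0.05 and -0.07. That typical offset at like signal was smaller than the list medians of -0.21 and -0.15. Among the signal-matched random lists, the glycolysis and hypoxia list had percentile 0 (none of 10000 lists had a median as low). The cholesterol list had percentile 0.83. The random lists held genes drawn independently and take no account of correlation within a list. The percentiles therefore do not exclude the signal-dependent offset as the whole cause. The list calls did not rest on control replicate 3 alone, the array that stood apart: without it the camera adjusted p with the preset correlation was 9.12e-06 and 6.92e-07. That form of the test also called lists in splits that mixed the genotypes, so it cannot exclude other effects of single arrays. An offset of another kind also stays open. The 45 array control probe sets not named for mouse genes had a median of -0.19, close to the medians of the lists (-0.21 and -0.15). The 3' minus 5' difference of actin was 1.02 to 1.30 on the Sox3 arrays against 1.33 to 1.39 on the control arrays. That of Gapdh went the other way (0.98 to 1.16 against 0.96 to 0.99). A difference in cell density, oxygen or medium between the cultures of the 2 genotypes was not tested, and neither was an effect of Sox3 itself, so both stay open.

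Crabp1, Nr2f1, Meis2 and Hoxb1 fell by 0.91 on average on the log2 scale, a size that follows in part from their being chosen after their values were seen. Weaker retinoic acid signalling in the Sox3 cells stays open: the other 21 measured genes of the retinoic acid list went both ways, with a mean log2 difference of -0.030 (95% interval -0.17 to 0.11), which decides nothing. Cyclic loess kept 91% of the fall. That outcome too was fixed in advance, since the median log2 differences over the deciles of signal were only -0.08 to 0.05. An effect of Sox3 itself was not tested and stays open.

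The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 255 probe sets higher and 536 lower, and the highest other split gave 0 in each case, so 1 of 10 splits gave as many. Each other split mixes the genotypes on both sides. Part of the genotype difference remains in it, and the rest widens the spread within its groups. A count of 0 there was therefore nearly fixed in advance. For gene lists past the camera threshold the real split gave 6 and the highest other 9, and 3 of 10 splits gave as many. Of the 6 called lists, 5 had their smallest p in the real split, whereas the cell cycle list had a p as small in 5 of 10 splits. The lists were called on the real split, so this rank is partly built in. Camera p was 5.51e-05 in the real split and 0.000136 in the nearest other for proneural genes, and 5.18e-06 and 5.34e-05 for cell cycle exit and p53 targets. It was 4.37e-07 and 0.00375 for glycolysis and hypoxia, 2.56e-07 and 0.000521 for cholesterol synthesis, and 0.000123 and 0.00299 for imprinted genes. The endoderm list, with camera p = 0.45 between the genotypes, reached p = 1.12e-09 in another split, and its estimated inter-gene correlation within groups was 0.46.

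The median log2 difference per chromosome lay between -0.018 and 0.017 over 20 chromosomes with at least 100 measured genes. Among the 64 array control probe sets 3 passed the threshold, all lower on the Sox3 arrays. In limma's test 28 of the 64 had an unadjusted p under 0.05, a larger share than the 5006 of 21876 tested probe sets.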
